A study of Mus musculus with 12 samples.

How the data were processed

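RNA sequencing libraries of total RNA from mouse small intestine and liver were compared between mice given LCWE and mice given PBS, with 3 libraries in each of 4 groups. Per the labels' protocols, RNA was extracted with TRIzol and treated with DNase I before a standard Illumina library preparation. The strandedness of the libraries is not stated, so reads of overlapping and antisense genes such as Hoxb3os cannot be told apart from those of their partners. Reads of near-identical genes, such as Saa1 and Saa2, the 7SL genes and the alpha defensins, may have been split or dropped between copies.

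The deposited expression table gives RPKM per gene and library, that is, reads per kilobase of gene length scaled to the reads of the library in the table, with no further scaling factor, as checked on the values. The submitters' processing notes name mm10, Trimmomatic 0.36, featureCounts, Subread 1.5.1 and edgeR 3.12.1 without their roles, and the aligner is not given in the sources used here. The table holds 34348 genes. Of its 16 library columns, 12 matched the samples and were used, and 4 matched no sample and were not used. A deposited differential table gives the authors' p-value, false discovery rate and log2 fold change for genes with p below 0.05 and a fold of at least 2, as checked on the values. It was used here only to count the genes it lists and those also tested or called here. Multiplying RPKM by gene length gave whole reads for 100% of values above 0 within a tolerance of 0.001, so the reads assigned to genes in each library are known. They ranged from 30294594 to 44921885. The correlation of log2 values across genes between libraries of a group ranged from 0.963 to 0.989.

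Groups were taken from the labels. The tests, filter, gene lists, rule for named genes and alternatives were chosen before the data were examined, except for voom, the 3 further gene lists under other observations and the tests named there as chosen later. Genes with an RPKM of at least 0.5 in at least 3 libraries of the tissue were tested on log2(RPKM + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend, two-sided, Benjamini-Hochberg adjusted, called at an adjusted p below 0.05). Each tissue was fitted apart. Fold changes are on the log2(RPKM + 0.5) scale, which understates the change of low genes. The difference between tissues was tested as the liver effect minus the intestinal effect in 1 fit over the 4 groups. Overlap between tissues was tested with a 1-sided Fisher's exact test. An exact permutation test of 3 against 3 libraries cannot give a two-sided p below 0.1, so single genes were tested with limma only.

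There were 34 gene lists, of which 27 were tried in the intestine and 23 in liver. They were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a tissue. Lists with under 5 tested genes got no test, and members absent from the table (3 of exocrine pancreas and 1 of erythroid markers) were not analysed here. Camera compares a list with all other genes, so its direction can differ from the sign of the list's median. Counts of members past the threshold are given over all genes and adjusted over the list alone. The members counted are those that passed the filter, which can be far fewer than those listed.

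The named genes are, per tissue, the 12 largest rises and 12 largest falls among genes that passed, whose groups did not overlap and whose mean RPKM was at least 1 in one group. Predicted or clone names, antibody and T cell receptor segments, ribosomal pseudogenes and mitochondrial genes were left out. Where fewer than 12 passed, genes with the smallest p in that direction filled the number and are said not to pass. Added to these are the 3 members of each list with the smallest p in that tissue, the 6 genes with the smallest p for the tissue difference, up to 6 genes that passed in both tissues (there were none) and Alb and Fabp2. A further gene that this rule selects is not reported here, and no other took its place. Other members of a list and the genes along the intestine given per library were singled out after their values were seen. Positions are those of the deposited expression table. In the GENCODE M21 annotation of mm10, 32795 of 34348 symbols (95.5%) and 174 of 175 named genes were matched, with Erdr1 unmatched. The positions of these 174 genes overlapped the annotation on the same strand, with ends that differ slightly for some.

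The alternatives were pseudocounts of 0.1 and 1, no filter, a filter at RPKM 1, quantile and median-ratio scaling, robust moderation, array weights (whose estimation did not converge for the intestine or for the 4 groups together), a fold of at least 2, 1 fit over 4 groups, the replicate number as a block, leaving out each library in turn, and, added after seeing the data, limma voom on the recovered reads. The procedure was tested on simulated data with 200 changed genes. In the simulated intestine of 17217 genes, 47% of 2-fold and 76% of 4-fold changes were recovered, and 8.21% of calls fell on unchanged genes. In the simulated liver of 13976 genes, 57% and 88% were recovered, with 7.05% of calls on unchanged genes. For the tissue difference over 18415 genes, 31% and 74% were recovered, with 11.0% of calls on unchanged genes. With no gene changed, 0 genes were called in each simulation. Each simulation was 1 draw, its genes were drawn independently, and the changed genes had a mean RPKM of at least 1. Real genes vary together (estimated correlation 0.87 within the intestinal cell cycle list), so these shares do not measure the power of the real comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.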

Results

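Total RNA from the small intestine and the liver of C57BL/6 mice was sequenced. Per the labels, the mice had received either LCWE or phosphate-buffered saline (PBS) as the control. Column names of the authors' differential table read LCWECFA for the treated groups, and the sources used here do not say what CFA stands for, so an effect of LCWE below means the difference of these groups, with or without a further agent. The labels do not spell out LCWE, which is the usual abbreviation for a cell wall extract of Lactobacillus casei used to induce a vasculitis in mice that serves as a model of Kawasaki disease. There were 4 groups with 3 libraries each, 12 libraries in all. The libraries keep the replicate numbers of the labels, which are 2, 3 and 4 for PBS and 1, 2 and 4 for LCWE in both tissues. The labels do not say whether libraries come from separate animals, so p-values measure the spread between these samples, which may be technical in part. Between 30294594 and 40253006 reads were assigned to genes in the intestinal libraries and between 34741958 and 44921885 in the liver libraries. Between 16966 and 17969 genes reached an RPKM (reads per kilobase of gene length, scaled to the reads of the library) of 0.5 in the intestine, and between 13557 and 14474 did so in liver.

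The identity of each tissue was read from Alb, which encodes serum albumin made by hepatocytes, and Fabp2, which encodes the fatty acid binding protein of enterocytes. In the liver, Alb stood at 23555, 14595 and 13375 RPKM in PBS replicates 2, 3 and 4 and at 10519, 12340 and 13391 RPKM in LCWE replicates 1, 2 and 4. In the intestine, Alb stood at 52.9, 60.2 and 59.2 RPKM in PBS and at 51.6, 60.2 and 145 RPKM in LCWE. Intestinal Fabp2 stood at 9408, 9206 and 5747 RPKM in PBS and at 3350, 2656 and 676 RPKM in LCWE. Liver Fabp2 stood at 113, 70.4 and 71.0 RPKM in PBS and at 47.5, 38.6 and 47.7 RPKM in LCWE. The 10 most abundant genes took between 4.94% and 6.87% of reads in the intestine and between 15.3% and 20.4% in liver, and the highest share belonged to liver PBS replicate 2. That library also held 0.0116% of its reads in haemoglobin genes, against 0.00214% to 0.00368% in the other liver libraries.

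The liver comparison asks how the liver transcriptome differs between LCWE-treated and control mice. Among the named genes, the 3 largest rises were of genes of the acute phase, which encode serum proteins that hepatocytes make in inflammation. Saa2, a serum amyloid A, rose from 11.6 ± 3.81 to 611 ± 220 RPKM (mean ± SD, n = 3 per group, as for all values below), which was 50.3-fold on the log2(RPKM + 0.5) scale. Also risen were 7 of 8 tested genes of MHC class II antigen presentation, 11 of 29 interferon response genes, 12 of 17 markers of monocytes and macrophages and 6 of 7 markers of neutrophils. Only these 7 of 18 listed neutrophil markers passed the filter, in part through their LCWE levels. G6pc, which encodes the last enzyme of glucose release, and Fgf21, a fasting hormone of the liver, fell, and 21 of 22 genes of cholesterol synthesis were lower. The RNA of the signal recognition particle (7SL) and 7SK RNA, which restrains transcription elongation, also fell.

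In all, 582 of 14404 tested genes changed in liver by limma, 489 of them upward and 93 downward, and 234 rose and 36 fell by at least 2-fold. Upward changes made up 84.0% of the calls, against 73.5% of 465 calls after quantile scaling (342 rose, 123 fell) and 73.8% of 478 after median-ratio scaling (353 rose, 125 fell), and 66.2% of 1902 with array weights. Further settings that moved the count by over 1.5 times were 1 fit over the 4 groups, with 987 calls (82.4% upward), no filter, with 335 (84.2% upward), and a fold of at least 2, with 270. The replicate number as a block gave 24 calls, of which 12 rose and 12 fell. It joins PBS and LCWE libraries of equal number and so rests on numbers 2 and 4 alone. The groups did not overlap for 27.5% of genes, where chance gives 10%. An unadjusted p below 0.05 was seen for 2697 genes, where 720.2 would be expected by chance. With limma voom on reads recovered from the RPKM values, 730 genes were called, 536 of them shared. The authors' deposited table lists 797 genes for this comparison, 625 of them at a false discovery rate below 0.05, and 339 of those 625 were called here. Only 595 of the 797 were tested here, so some of the 625 could not be called. Each library weighed on the count. It was 943 without PBS replicate 2, 113 without PBS replicate 3, 235 without PBS replicate 4, 88 without LCWE replicate 1, 55 without LCWE replicate 2 and 249 without LCWE replicate 4.

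The acute phase list was higher in LCWE livers, with 9 of 23 tested members risen, 18 risen when adjusted over the list alone, and all 23 above the control mean. Its median log2 fold change was 1.15 (camera with a preset correlation, adjusted p = 1.82e-13; adjusted p = 0.161 with an estimated correlation). Saa2 (mm10 chromosome 7, 46751790 to 46754313) rose 50.3-fold with an adjusted p of 0.00327, and its neighbour Saa1 (chromosome 7, 46740497 to 46742980) rose 29.1-fold, from 11.5 ± 7.26 to 316 ± 60.7 RPKM. Reads of these near-identical genes may be shared between them. Orm2 (chromosome 4, 63362449 to 63365878), an acid glycoprotein, rose 25.0-fold, from 18.3 ± 6.62 to 587 ± 437 RPKM, with 580, 1028 and 153 RPKM in the LCWE livers. Lcn2 (chromosome 2, 32384633 to 32388252), which encodes an iron-withholding lipocalin, rose 11.8-fold, from 0.559 ± 0.319 to 13.5 ± 7.71 RPKM. Lbp, which encodes the lipopolysaccharide binding protein, rose 2.28-fold, from 5.86 to 14.1 RPKM. The metal-binding metallothioneins Mt2 (chromosome 8, 94172664 to 94173568) and Mt1 rose 23.6-fold and 8.06-fold. Mt2 stood at 8.60, 33.3 and 27.7 RPKM in the LCWE livers, against a control mean of 0.426. Mt1 did not pass with voom (adjusted p = 0.0531). Creld2, a gene of endoplasmic reticulum stress, rose 6.30-fold, from 62.6 ± 19.7 to 384 ± 21.5 RPKM, and Moxd1, a monooxygenase-like gene, rose 15.5-fold.

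**Figure D1:**
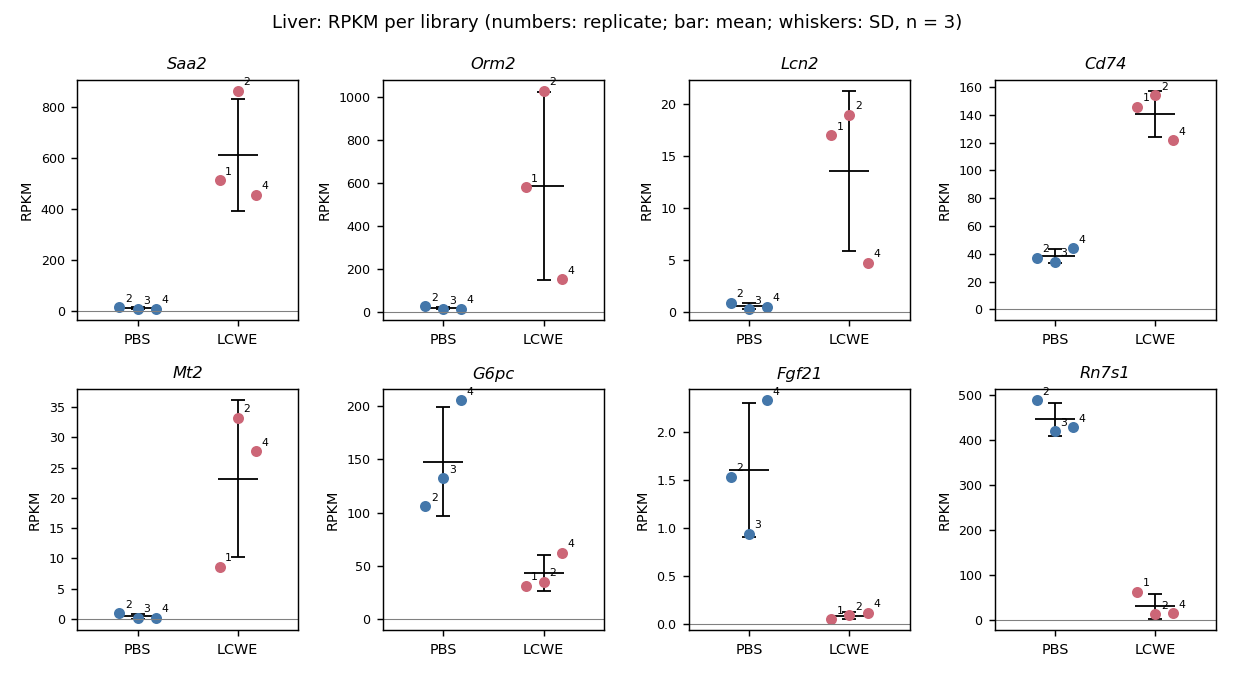
RPKM of 8 liver genes in each PBS and LCWE library on linear axes, with replicate numbers beside the points, the mean as a bar and the SD as whiskers (n = 3 per group). Saa2 lies between 457 and 862 RPKM in the LCWE livers and at or below 15.8 RPKM in the PBS livers.

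Of 8 tested genes of MHC class II presentation, 7 rose, all 8 when adjusted over the list alone, with a median log2 fold change of 1.66 (adjusted p = 4.19e-10; adjusted p = 0.128 with an estimated correlation). Cd74 (chromosome 18, 60803848 to 60812646), the invariant chain that guides class II molecules, rose 3.62-fold, from 38.5 ± 5.06 to 141 ± 16.7 RPKM, and H2-Eb1 rose 4.10-fold, from 20.5 to 86.1 RPKM. Of 29 interferon response genes, 11 rose, 18 when adjusted over the list alone, and 28 were higher, with a median of 0.66 (adjusted p = 1.42e-12; adjusted p = 0.0665 with an estimated correlation). The guanylate binding proteins Gbp3 and Gbp2 rose 2.71-fold and 3.37-fold, and Cxcl9, which attracts T cells, rose 4.42-fold, from 5.15 to 23.9 RPKM. The very large GTPase gene Gvin1 rose 8.53-fold and the T cell specific GTPase gene Tgtp1 rose 7.06-fold, and both have near-identical copies whose reads may be shared.

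Of 17 monocyte and macrophage markers, 12 rose, all 17 when adjusted over the list alone, with a median of 0.89 (adjusted p = 9.41e-13; adjusted p = 0.0562 with an estimated correlation). Marco, a scavenger receptor of macrophages, rose 7.80-fold, from 11.9, 21.7 and 43.4 RPKM to 108, 165 and 319 RPKM. Csf1r, the receptor for the macrophage growth factor, rose 2.05-fold, and Lyz2, a lysozyme, rose 2.76-fold. Of 18 listed neutrophil markers, 7 passed the filter. Of these 7, 6 rose, all 7 when adjusted over the list alone, with a median of 1.21 (adjusted p = 1.74e-07; adjusted p = 0.0562 with an estimated correlation). The calcium-binding protein gene S100a9 rose 8.01-fold, from 2.15 to 20.1 ± 9.02 RPKM. Of 7 T and NK cell markers that passed the filter, of 18 listed, 3 rose, 5 when adjusted over the list alone, and all 7 were higher (median 0.76; adjusted p = 9.32e-05; adjusted p = 0.0665 with an estimated correlation), among them the granzyme gene Gzmb, from 0.466 to 1.62 RPKM. With any 1 LCWE library left out, under 5 members of the neutrophil list and of the T and NK list were tested. Some members thus passed the filter only with their LCWE levels and could hardly be lower, so these counts follow in part from the filter. Of 5 B and plasma cell markers, 2 rose, the same number when adjusted over the list alone, and 4 were higher (median 0.79; adjusted p = 0.0397; adjusted p = 0.327 with an estimated correlation). These 2 were Igkc, the kappa light chain, which rose 2.87-fold, and Jchain, which joins secreted antibodies. Over the other settings, adjusted p for this list ran from 0.00389 to 0.289, the highest with no filter, and it was 0.115 without PBS replicate 3 and 0.139 without PBS replicate 4.

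Of 16 genes for cytokines, chemokines and adhesion molecules, 6 rose, 9 when adjusted over the list alone, and 12 were higher (median 0.70; adjusted p = 0.000417; adjusted p = 0.128 with an estimated correlation). Tnfaip3, a brake on NF-kB signalling, rose from 0.314 to 1.55 RPKM, Icam1, an adhesion molecule for leukocytes, rose 2.25-fold, and Vcam1 rose from 0.843 to 2.48 RPKM. Of 11 pattern recognition and inflammasome genes, 2 rose, 7 when adjusted over the list alone, and 10 were higher (median 0.45; adjusted p = 0.000399; adjusted p = 0.0665 with an estimated correlation). They were Irak3, an inhibitor of Toll-like receptor signalling, which rose 2.95-fold, and Cd14, a coreceptor for lipopolysaccharide. Of 16 genes of extracellular matrix and fibroblasts, 1 rose, 8 when adjusted over the list alone, and all 16 were higher (median 0.44; adjusted p = 3.06e-05; adjusted p = 0.128 with an estimated correlation). It was Vim, an intermediate filament of mesenchymal cells and leukocytes, from 4.78 to 11.7 RPKM.

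Of 22 genes of cholesterol synthesis, 4 fell, 14 when adjusted over the list alone, and 21 were lower (median -0.57; adjusted p = 6.60e-13; adjusted p = 0.0665 with an estimated correlation). Insig1, a sterol sensor, fell from 101 to 50 RPKM, and the synthesis enzyme genes Sc5d and Cyp51 fell from 114 to 55.4 RPKM and from 39.5 to 24.9 RPKM. Of 17 genes of fatty acid synthesis, none passed, over all genes or adjusted over the list alone, and 15 were lower (median -0.57; adjusted p = 2.49e-05; adjusted p = 0.338 with an estimated correlation). Mid1ip1, a lipogenic regulator outside that list, fell from 42.2 to 19.7 RPKM. Of 24 genes of fatty acid oxidation and PPAR alpha targets, 1 fell, 4 when adjusted over the list alone, and 20 were lower (median -0.26; adjusted p = 5.86e-07; adjusted p = 0.161 with an estimated correlation). It was Fgf21, from 1.6 ± 0.696 to 0.0900 ± 0.033 RPKM. Acot3, a peroxisomal thioesterase gene, fell from 1.06 to 0.155 RPKM.

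Of 24 genes of bile acid synthesis and transport, 1 fell, 15 were lower, and 1 rose and 3 fell when adjusted over the list alone. The 1 past the threshold over all genes was Abcg8, a sterol exporter, from 8.07 to 5.01 RPKM (median of the list -0.16; adjusted p = 0.00451; adjusted p = 0.218 with an estimated correlation). Of 24 genes of xenobiotic metabolism, 17 were lower, but the 1 gene that passed rose, and 1 rose and 3 fell when adjusted over the list alone (median -0.22; adjusted p = 0.000528; adjusted p = 0.133 with an estimated correlation). It was Cyp2b10, a drug-inducible cytochrome, which rose 3.35-fold, from 0.170 to 1.76 RPKM. Of 16 hepatocyte secreted proteins, none passed, 1 fell when adjusted over the list alone (Ttr, the thyroxine carrier transthyretin, 5033 ± 636 against 3312 ± 161 RPKM), and 12 were lower (median -0.22; adjusted p = 0.00118; adjusted p = 0.257 with an estimated correlation). None of 7 erythroid markers passed, over all genes or adjusted over the list alone, and all 7 were lower (median -0.55; adjusted p = 0.0162; adjusted p = 0.234 with an estimated correlation). The haemoglobin share was highest in liver PBS replicate 2, and adjusted p for the erythroid list was 0.309 without that library and 0.0545 without LCWE replicate 1, in a range of 0.000522 to 0.309 over the other settings. Quantile scaling ended 4 of these calls, with adjusted p of 0.176 for bile acids (range 0.00135 to 0.176), 0.0889 for xenobiotic metabolism (2.10e-05 to 0.0889), 0.0521 for secreted proteins (0.000324 to 0.0521) and 0.0517 for erythroid markers.

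G6pc (chromosome 11, 101367561 to 101377903) fell from 148 ± 51.6 to 42.9 ± 17.0 RPKM, and the glycogen synthase gene Gys2 fell from 42.8 to 27.8 RPKM. Their list, glucose and amino acid metabolism, did not pass as a whole (21 tested; 1 rose and 2 fell when adjusted over the list alone; adjusted p = 0.120, and 0.00689 without LCWE replicate 4, in a range of 0.00689 to 0.613). Ces1d, a carboxylesterase gene, fell from 143 to 56.1 RPKM, Clstn3, a calsyntenin gene, from 3.32 to 1.23 RPKM, and the microRNA gene Mir7046 from 1.26 to 0.246 RPKM, which did not pass with voom (adjusted p = 0.191). Of 14 immediate early and stress genes, 1 fell, 2 when adjusted over the list alone (list adjusted p = 0.217, and 0.00521 without LCWE replicate 4, in a range of 0.00521 to 0.733). It was Dusp1, a phosphatase that shuts off stress kinases, from 7.02 to 3.18 RPKM. The list's median was 0.31 and its mean 0.07, while the test placed it below the other genes. Of 13 cell cycle genes, 1 rose, also when adjusted over the list alone (Mki67, a proliferation marker, from 1.21 to 3.23 RPKM; list adjusted p = 0.133, and 0.0141 without LCWE replicate 1 and 0.032 without LCWE replicate 2, in a range of 0.00253 to 0.650).

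No gene of the other 3 liver lists passed, over all genes or adjusted over the list alone. These were 12 circadian clock genes (adjusted p = 0.268; median 0.10, or -0.04 after quantile scaling; mean -0.03, tested as lower) and 21 complement and coagulation genes (16 higher; median -0.04 after median-ratio scaling; adjusted p = 0.385, and 0.047 without PBS replicate 2). The last were 5 cholangiocyte markers (adjusted p = 0.644; median 0.07, or -0.02 after median-ratio scaling; mean 0.15, yet tested as lower). Adjusted p ranged from 0.0225 to 0.931 for the complement list over the other settings, and the lowest came with array weights.

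Among the named genes, the 4 largest falls in liver were of short structural RNAs. Rn7s1 (chromosome 12, 69159295 to 69159594), a 7SL gene, fell from 446 ± 37.0 to 31.0 ± 28.0 RPKM. Its near-identical copies Rn7s2 and Rn7s6 (chromosome 6, 69516339 to 69516629) fell from 58.9 to 2.16 RPKM and from 32.2 ± 3.28 to 0.121 ± 0.209 RPKM, with 2 LCWE libraries at 0 for Rn7s6. Rn7sk (chromosome 9, 78175303 to 78175633), the 7SK gene, fell from 14.8 to 2.02 RPKM. The log2 fold changes of Rn7s6 and Rn7s1 were -5.77 (adjusted p = 0.00093) and -4.18.

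Of the 56 named liver genes that passed, 48 of 52 still tested passed without PBS replicate 2, 20 of 52 without PBS replicate 3 and 30 of 52 without PBS replicate 4. Of 50 still tested, 23 passed without LCWE replicate 1, 16 without LCWE replicate 2 and 36 without LCWE replicate 4. None of these genes changed direction in those fits.

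The intestinal comparison asks the same of the small intestine. In the LCWE libraries, 21 of 23 genes of nutrient absorption, which mature enterocytes express, were lower, and so were all 7 genes of adipose tissue. Apoa4, an apolipoprotein that enterocytes secrete with dietary fat, stood at 3738 ± 2779 RPKM in PBS and 293 ± 164 RPKM in LCWE. By contrast, 22 of 23 cell cycle genes and all 19 extracellular matrix genes were higher, by smaller amounts. No single gene passed the test over all genes, so the values of single genes below are given without such a call. Members said to rise or fall when adjusted over the list alone are not corrected across the 27 lists.

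Of 17510 genes tested by limma in the intestine, 0 passed (lowest adjusted p = 0.154). An unadjusted p below 0.05 was seen for 2202 genes, 1346 higher and 856 lower, where 875.5 would be expected by chance. Voom also called 0 genes (lowest adjusted p = 0.0863). The groups did not overlap for 19.3% of genes, where chance gives 10%. The authors' deposited table lists 220 genes for this comparison, 42 higher and 178 lower, with 0 at a false discovery rate below 0.05. Leaving out LCWE replicate 1 gave 70 calls (13 rose, 57 fell) and leaving out LCWE replicate 2 gave 4, while 1 fit over all 4 groups gave 243 (94 rose, 149 fell). The median log2 fold change of all intestinal genes was 0.11, against 0.01 after median-ratio scaling and 0.03 after quantile scaling, and the list tests compare a list with all other genes.

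Of 23 enterocyte absorption genes, 21 were lower and 2 higher, with a median of -1.20 and of -1.31 after median-ratio scaling (adjusted p = 3.09e-12; adjusted p = 0.737 with an estimated correlation). Adjusted over the list alone, 11 fell and 1 rose. Among them were Apoa4 (log2 fold change -3.56), Fabp2 (-2.12) and Alpi, the intestinal alkaline phosphatase, at 64.0 RPKM in PBS and 23.6 RPKM in LCWE. The exception was Slc40a1, the iron exporter ferroportin, at 0.672 RPKM in PBS and 1.95 RPKM in LCWE. All 7 adipose tissue genes were lower, with a median of -1.61 and of -1.71 after median-ratio scaling (adjusted p = 1.61e-08; adjusted p = 0.367 with an estimated correlation), and 4 fell when adjusted over the list alone. They included Cidec, a lipid droplet gene, at 31.2 ± 1.44 against 7.03 ± 4.63 RPKM, and Adipoq, the fat cell hormone adiponectin, which stood at 1.18, 8.01 and 14.2 RPKM in PBS and at 0.612, 0.250 and 0.128 RPKM in LCWE. The list was chosen to mark fat cells that a tissue piece could hold, and how much fat the pieces held was not tested.

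**Figure D2:**
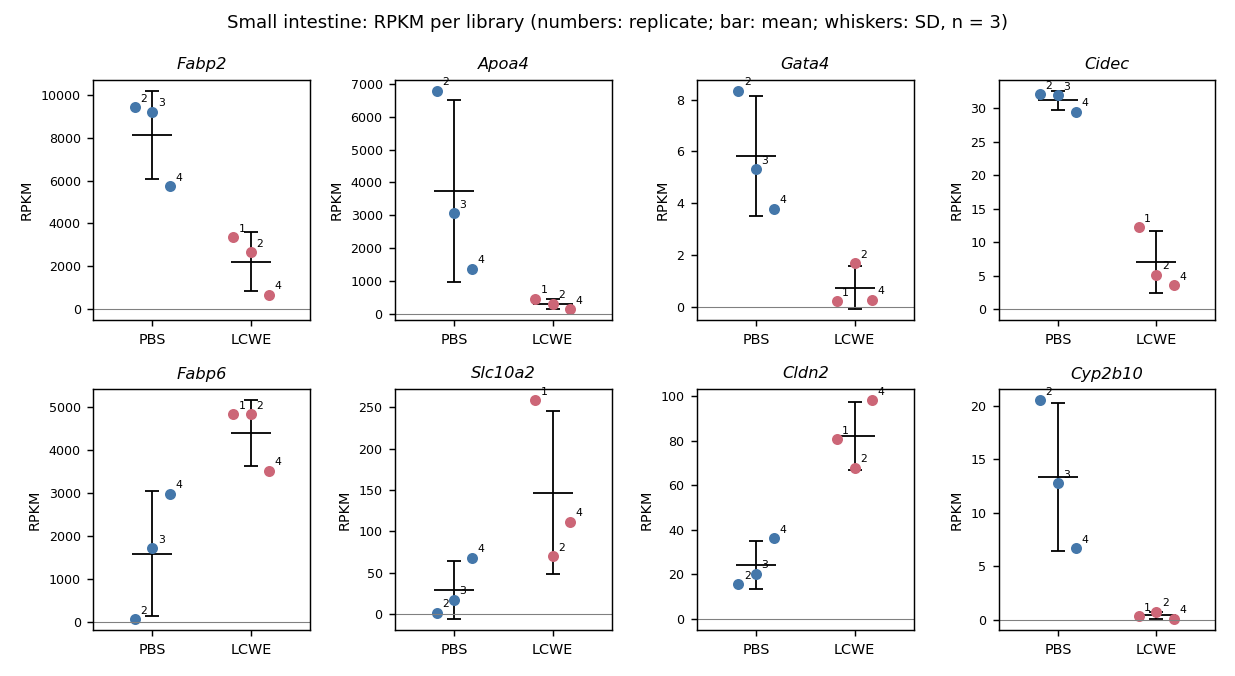
RPKM of 8 genes in each intestinal PBS and LCWE library on linear axes, with replicate numbers beside the points, the mean as a bar and the SD as whiskers (n = 3 per group). Fabp2 lies between 5747 and 9408 RPKM in PBS and between 676 and 3350 RPKM in LCWE, and no gene shown passed the test over all genes.

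Genes that differ along the length of the small intestine varied between libraries in both groups. Gata4, a transcription factor of the proximal intestine, stood at 8.34, 5.31 and 3.79 RPKM in PBS replicates 2, 3 and 4 and at 0.216, 1.68 and 0.280 RPKM in LCWE replicates 1, 2 and 4. Fabp6, the bile acid binding protein of the ileum, stood at 69.4, 1716 and 2991 RPKM in PBS and at 4837, 4843 and 3517 RPKM in LCWE. Slc10a2, the bile acid importer of the ileum, stood at 1.51, 17.6 and 68.4 RPKM in PBS and at 259, 70.4 and 112 RPKM in LCWE. Of 9 ileal bile acid handling genes, 7 were higher with a median of 0.57, and 2 rose and 2 fell when adjusted over the list alone (list adjusted p = 0.837). The risen ones were Nr1h4, the bile acid receptor, and Abcc3, a bile salt exporter. The fallen ones were Gata4 and Abcc2, an apical conjugate exporter. Gata4 is a factor of the proximal intestine, so its fall does not speak against a rise of ileal genes, although the list test counted it that way.

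Of 23 cell cycle genes, 22 were higher, with a median of 0.24 and of 0.13 after median-ratio scaling (adjusted p = 0.0149; adjusted p = 0.953 with an estimated correlation), and none passed when adjusted over the list alone. Mki67 stood at 80.9 ± 10.8 against 98.8 ± 15.2 RPKM. All 19 extracellular matrix and fibroblast genes were higher, with a median of 0.37 and of 0.25 after median-ratio scaling (adjusted p = 0.0279; adjusted p = 0.953 with an estimated correlation), and none passed when adjusted over the list alone. Of 16 immediate early and stress genes, 11 were lower, with a median of -0.07 and of -0.18 after median-ratio scaling (adjusted p = 0.0149; adjusted p = 0.737 with an estimated correlation), and none passed when adjusted over the list alone. Fos, an early transcription factor, stood at 30.7 ± 11.4 against 13.3 ± 4.14 RPKM. These 3 calls depended on single libraries. Adjusted p for cell cycle was 0.301 without PBS replicate 4 and 0.157 without LCWE replicate 2, in a range of 4.30e-05 to 0.301. For extracellular matrix it was 0.176 without PBS replicate 2, 0.137 without LCWE replicate 2, 0.260 without LCWE replicate 4 and 0.0953 with a stricter filter, in a range of 1.20e-05 to 0.260. For immediate early genes it was 0.10 without PBS replicate 4, 0.137 without LCWE replicate 2 and 0.0603 after median-ratio scaling, in a range of 0.00072 to 0.137.

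The genes with the smallest p in the intestine did not pass. Among the lower ones, Cyp3a11 (mm10 chromosome 5, 145854426 to 145879964), a major drug-metabolising cytochrome, stood at 42.9 ± 6.04 RPKM in PBS and 7.34 ± 2.79 RPKM in LCWE (log2 fold change -2.52, adjusted p = 0.154). Cyp2b10 stood at 13.3 ± 6.95 against 0.410 ± 0.330 RPKM, Cyp4b1 at 21.6 ± 2.29 against 5.88 ± 1.69 RPKM, and Cyp2d22 at 3.93 against 1.91 RPKM. Cd36, a fatty acid transporter, stood at 6.89 ± 1.18 against 2.41 ± 0.176 RPKM, and Abcc2 at 21 ± 3.55 against 6.41 ± 1.61 RPKM. Guca2b, the gut hormone uroguanylin, stood at 88.0 ± 9.66 against 34.7 ± 5.06 RPKM, and Leap2, which encodes a peptide that opposes ghrelin, at 8.83 against 1.34 RPKM. Pcx (pyruvate carboxylase), Npl (sialic acid breakdown), Osgin1 and the microRNA gene Mir215 were also among the 12 lower genes with the smallest p.

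Among the higher ones, Cldn2, a pore-forming claudin of leaky epithelia, stood at 24.1 ± 10.8 RPKM in PBS and 82.3 ± 15.2 RPKM in LCWE (log2 fold change 1.83). Gcg, the precursor of the glucagon-like peptides, stood at 25.2 ± 3.62 against 45.1 ± 1.84 RPKM, and Klk1, a kallikrein, at 33.4 against 59.4 RPKM. Erdr1 stood at 43.0 ± 3.32 against 120 ± 29.5 RPKM. Ampd3 (AMP deaminase), Pdia5 (protein folding), the epithelial transcription factor Ehf, Arhgef10l, Sgf29, the antisense gene Hoxb3os and the microRNA genes Mir7648 and Mir719 completed the 12 higher genes with the smallest p. Adjusted p for these 24 genes lay between 0.154 and 0.186.

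The other epithelial lists did not pass in the intestine. Of 14 goblet cell and mucus genes, 10 were higher, and Klk1, Agr2 and Atoh1 rose when adjusted over the list alone (list adjusted p = 0.0890). Of 19 tight junction and adhesion genes, 10 were higher with a median of 0.0048, or -0.11 after median-ratio scaling, and a mean of 0.07, while the test placed them lower (adjusted p = 0.462). Cldn2 and Cldn8 rose and Cldn15 and Cldn4 fell when adjusted over the list alone. Of 17 enteroendocrine and tuft cell genes, 12 were higher with a median of 0.07, or -0.04 after median-ratio scaling, and Gcg rose when adjusted over the list alone (adjusted p = 0.971). Of 15 Paneth cell genes, 8 were higher with a median of 0.02, or -0.09 after median-ratio scaling, and a mean of -0.02 (adjusted p = 0.246). Of 11 stem cell and crypt genes, 9 were higher (adjusted p = 0.363), and of 16 inducible antimicrobial genes, 10 were lower (adjusted p = 0.0671). None of the last 3 lists had a member that passed when adjusted over the list alone.

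Most immune lists had more higher than lower members in the intestine without passing. This held for 16 of 17 monocyte and macrophage markers (adjusted p = 0.0890), 14 of 17 T and NK cell markers (adjusted p = 0.144), 15 of 16 B and plasma cell markers (adjusted p = 0.147) and 12 of 16 pattern recognition genes (adjusted p = 0.197). It also held for 5 of 6 neutrophil markers (adjusted p = 0.197), 14 of 19 acute phase genes (adjusted p = 0.704), 14 of 20 cytokine and adhesion genes (adjusted p = 0.971) and 7 of 10 MHC class II genes (adjusted p = 0.907), whose median of 0.08 turned to -0.04 after median-ratio scaling. Of 30 interferon response genes, 14 were higher and 16 lower, with a median of -0.01 (adjusted p = 0.179). Cd177, a neutrophil surface protein at 2.80 against 8.43 RPKM, rose when adjusted over its list alone, and no other member of these lists did.

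Of the remaining intestinal lists, 19 of 22 cholesterol synthesis genes were higher (adjusted p = 0.440), and 13 of 15 smooth muscle and enteric nerve genes were higher with a median of 0.10, or -0.0077 after median-ratio scaling (adjusted p = 0.907). All 5 erythroid markers were lower (adjusted p = 0.259). Of 15 circadian clock genes, 7 were higher, with a median of -0.03 and a mean of 0.07, tested as lower (adjusted p = 0.413). Of 21 genes of fatty acid oxidation, 11 were higher with a median of 0.03, or -0.08 after median-ratio scaling, and a mean of -0.08, tested as lower, and Cd36 fell when adjusted over the list alone (adjusted p = 0.138). The 3 exocrine pancreas genes measured were lower, with a median of -0.24, and were too few for a test. No other member of these lists passed when adjusted over the list alone.

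Scaling or a left-out library brought some of these lists past the threshold. After quantile and median-ratio scaling, adjusted p was 0.0392 and 0.0213 for monocyte and macrophage markers (range 0.000729 to 0.279 over the other settings), 0.0392 and 0.0461 for B and plasma cell markers (0.00618 to 0.713), and 0.0175 and 0.0461 for goblet cells (0.00681 to 0.489). Without LCWE replicate 1 it was 0.000953 for interferon response, 0.000825 for macrophages, 0.00432 for inducible antimicrobial genes, 0.0154 for tight junctions and 0.0374 for stem cells. Without LCWE replicate 4 it was 0.00681 for Paneth and goblet cells, 0.0254 for T and NK cells and 0.0268 for cholesterol synthesis. Without PBS replicate 2 it was 0.00334 for T and NK cells. Without PBS replicate 3 it was 0.0363 for macrophages and B cells, 0.0393 for goblet cells and 0.0181 for antimicrobial genes. Without PBS replicate 4 it was 0.00687 for interferon response, 0.00422 for cholesterol synthesis, 0.042 for B cells and 0.0346 for goblet cells.

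**Figure D3:**
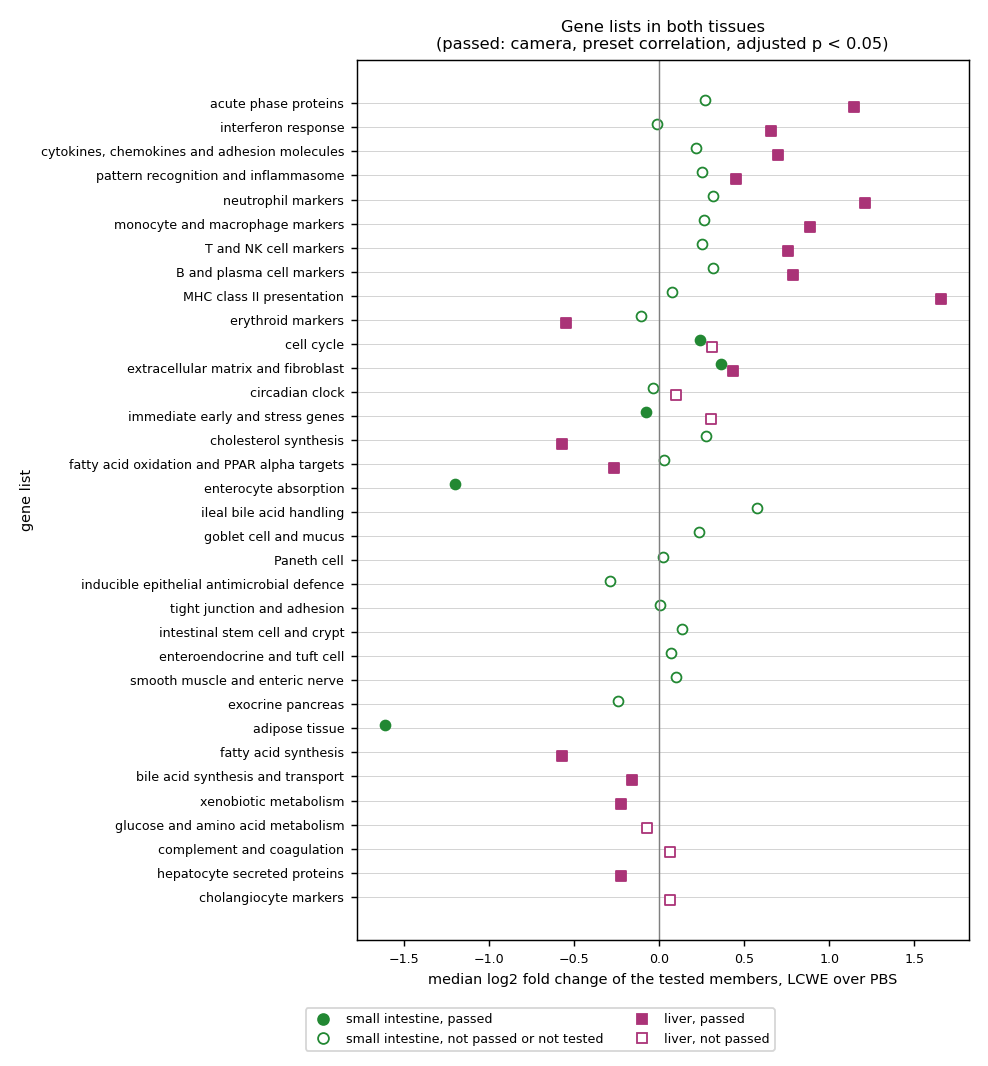
Median log2 fold change (LCWE over PBS) of the tested members of each gene list in the small intestine (circles) and liver (squares), with filled symbols for lists that passed camera with a preset correlation. In all, 17 of 23 lists passed in liver and 5 of 26 in the intestine, and 0 passed in either tissue with an estimated correlation; medians that change sign after median-ratio or quantile scaling are those of liver cholangiocyte, complement and circadian clock genes and of intestinal MHC class II, Paneth, enteroendocrine, fatty acid oxidation, smooth muscle and tight junction genes, and none of these passed.

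The tissue comparison asks which responses to LCWE differ between liver and intestine. Named genes of the acute phase (Saa2, Orm2 and Lcn2), of antigen presentation (Cd74, H2-Eb1 and H2-Aa) and of the interferon response (Cxcl9, Cxcl10 and Gbp3) had a larger LCWE effect in liver than in the intestine. The effects on the cytochrome genes Cyp2b10, Cyp3a11 and Cyp4b1 also differed, with negative log2 fold changes in the intestine. Intestinal Cyp2b10 also fell within the PBS libraries, at 20.5, 12.8 and 6.67 RPKM in replicates 2, 3 and 4, in the same order as Gata4, so its difference may follow the position of the piece. Intestinal Cxcl10 fell in that order too and was lower still in each LCWE library, so its difference may also follow position. The Saa2 effect was larger in liver by 5.73 on the log2 scale (SE 0.34, adjusted p = 6.14e-05), with log2 fold changes of 5.65 in liver and -0.08 in the intestine. Intestinal Saa2 stood at only 1.08 to 1.31 RPKM. The median Alb level of the intestinal libraries, 0.408% of that in liver, would at the same share of mean liver Saa2 give 1.27 RPKM, so intestinal Saa2 may be liver signal. The same holds for intestinal Orm2, where that share would give 1.23 of 1.43 RPKM. Over the named genes that differ, it would give at least 10% of the intestinal level for 7, which also include Acot3 (67.3%), Marco (28.8%), BC023105 (19.9%), Lcn2 (11.4%) and Fgf21 (11.3%). BC023105, Lcn2, Fgf21 and Acot3 were below the filter in the intestine. For these genes the difference may therefore say little or nothing of a response in the intestine. The Cyp2b10 effect differed by 5.60 (SE 0.51, adjusted p = 0.00178), with 1.75 in liver and -3.86 in the intestine. The Cd74 effect differed by 1.79 (SE 0.19, adjusted p = 0.00548), with 1.85 in liver and 0.07 in the intestine, or -0.05 after median-ratio scaling. Cd74 stood at 620 to 808 RPKM in the intestinal libraries and at 34.3 to 44.1 RPKM in the PBS livers. H2-Eb1 stood at 282 to 375 RPKM and at 17.6 to 24.7 RPKM. At such levels an equal rise in RPKM gives a smaller log2 fold change in the intestine. For the class II genes the difference therefore does not show a smaller rise in RPKM there. The effect on the 7SL gene Rn7s6 was lower in liver by -4.98 (SE 0.44, adjusted p = 0.00178).

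The difference of the effects, liver minus intestine, passed for 137 of 18619 genes in 1 limma fit over the 4 groups, above 0 for 99 and below 0 for 38. The count was 206 after median-ratio scaling, 161 with voom and 113 after quantile scaling. It was 12 (9 above 0, 3 below) with a block that joins intestinal and liver libraries of equal treatment and number. The labels do not say whether such libraries share an animal. The 6 genes with the smallest p were Saa2, Cyp2b10, Rn7s6, Cd74, the processed pseudogene BC023105 (difference 2.52) and Gm4070 (2.22), a predicted gene close in sequence to Gvin1. BC023105 did not pass with voom (adjusted p = 0.0732). Leaving out intestinal libraries gave 58, 24 and 210 genes without PBS replicates 2, 3 and 4 and 461 and 32 genes without LCWE replicates 1 and 4. Leaving out liver libraries gave 20 and 88 genes without PBS replicates 3 and 4 and 38 and 31 genes without LCWE replicates 1 and 2.

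No gene passed in both tissues, since 0 passed in the intestine by limma and 0 with voom, but 9 did so with 1 fit over the 4 groups, and 748 with array weights, whose estimation did not converge for the intestine. At an unadjusted p below 0.05 in both tissues, 292 of 13470 genes tested in both were higher in both, where independent lists would share 134, and 96 were lower in both, where they would share 33.0 (1-sided Fisher's exact tests, p = 1.67e-42 and p = 5.64e-22). Opposite directions were seen for 38 and 58 genes, where independent lists would share 53.8 and 82.3. Genes are not independent replicates, so these p-values describe the gene lists and not the animals. Across genes the log2 fold changes of the tissues had a Pearson r of 0.197 and a Spearman rho of 0.205, and 60.3% of genes had the same sign. Of the 545 liver calls tested in the intestine, 80.2% had the same sign there.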

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

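The counts of other splits of the samples were planned, while the count of splits that keep the liver groups and the tests of the 3 patterns weighed here were chosen only after the result was seen.

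The LCWE effect of 37 named genes differed between liver and intestine in the test of the difference itself, with values above 0 for 25 genes and below 0 for 12. Values are the log2 fold change in liver minus that in the intestine. Among acute phase and metal-binding genes it was 5.73 for Saa2, 4.69 for Orm2, 3.40 for Lcn2 and 4.05 for Mt2. Among genes of antigen presentation and interferon response it was 1.79 for Cd74, 1.95 for H2-Eb1, 1.84 for H2-Aa, 2.28 for Cxcl9, 1.47 for Cxcl10, 0.99 for Gbp3, 2.67 for Gvin1 and 2.22 for Gm4070. Among genes of inflammation and immune cells it was 1.41 for Tnfaip3, 3.59 for Marco and 2.66 for S100a9. It was 4.0 for Moxd1, 1.89 for Creld2 and 2.52 for BC023105. Among genes lower in intestinal LCWE libraries it was 5.60 for Cyp2b10, 2.44 for Cyp3a11, 1.88 for Cyp4b1, 1.29 for Guca2b, 1.08 for Pcx, 1.46 for Npl and 1.51 for Cd36. Among genes higher in intestinal LCWE libraries it was -1.0 for Sgf29, -2.20 for Cldn2, -1.70 for Nr1h4, -0.93 for Gcg, -1.14 for Arhgef10l and -0.83 for Plin2. Among genes lower in liver it was -4.98 for Rn7s6, -4.03 for Rn7s2, -3.73 for Rn7s1, -1.27 for Mid1ip1, -1.82 for Fgf21 and -1.27 for Acot3. BC023105, Lcn2, Fgf21 and Acot3 were below the filter in the intestine, and Guca2b, Npl and Gcg in liver, so for them the value is that of a gene hardly expressed in the other tissue and no sign of a differing response. Cd74, H2-Eb1 and H2-Aa stood far higher in the intestine than in the PBS livers, so an equal rise in RPKM would give a smaller log2 fold change there. From PBS replicate 2 to 4 the intestinal levels of Cldn2, Nr1h4, Gcg and Arhgef10l rose in order. Those of Cyp2b10 and Cxcl10 fell, as Gata4 fell. In each LCWE library these genes lay beyond their PBS levels in the same direction. For them the position of the intestinal piece was therefore not separated from LCWE. Gata4 was lower in each intestinal LCWE library than in any PBS library, so position was not separated for the other intestinal effects either.

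The 137 genes with a tissue difference were set against 100 drawn splits of the samples within the tissues, of which 4 gave as many genes, the real one included. At that share chance can be excluded only for the parting of all libraries together, since most of these splits also break up the liver groups. Of the 20 splits that keep the real parting of the liver libraries, 5 gave as many genes, the real one included, so chance cannot be excluded for the intestinal groups, and the count may follow from the liver effect alone. The highest of the other splits gave 959 genes in both sets. That split keeps the real intestinal groups and swaps the liver labels, so it counts genes by the sum of the effects in the tissues and not by their difference. With the liver labels swapped, exchanging intestinal LCWE replicate 1 for PBS replicate 4 or 3 still gave 691 and 637 genes. What raises these counts was not tested. In liver the real split gave 582 genes and the highest of the other splits gave 1, and 1 of the 10 splits gave as many as the real one. In the intestine the real split gave 0 genes and so did each other split, 10 of 10. The 10 splits of a tissue are too few for a share under 0.05.

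Enterocyte absorption genes were lower in the intestinal LCWE libraries as a list, with a median log2 fold change of -1.20, but passed only with a preset correlation (adjusted p = 3.09e-12) and not with an estimated one (adjusted p = 0.737). LCWE replicate 4 alone, with the lowest Fabp2, is argued against, since adjusted p with the preset correlation was 6.96e-10 without it. A candidate explanation is a more distal piece of intestine in the LCWE group. The 10 tested Hox genes of paralogue groups 6 to 9, which mark distal positions, had a median log2 fold change of 0.72, and 9 of them were higher. The SE of that median, 0.46, was taken over the genes and does not measure the spread between libraries. A smaller share of enterocytes in the LCWE group cannot be told apart from a more distal piece. The mean log2 level of 6 ileal transport genes was 6.12 in PBS and 7.38 in LCWE. That difference of 1.26 had an SE of 0.85 over the libraries. These genes also follow position, with Fabp6 at 69.4, 1716 and 2991 RPKM in PBS replicates 2, 3 and 4, and Mep1a among them is also in the absorption list. A more distal piece could raise them at any share of enterocytes, so the test cannot decide on that share. A smaller share therefore stays open. A response of the enterocytes to LCWE also stays open and was not tested.

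Liver libraries held transcripts of Paneth and goblet cells, at a mean of 0.295% of the intestinal level for Paneth genes and 0.633% for goblet genes. Expression by the liver's own cells is argued against as the source of the set, since 91.3% of 23 abundant genes lay within 2 times of a median of 0.235% of the intestinal level. Reads carried over from the intestinal libraries are argued against as the source of all of them by the ratio of the goblet to the Paneth share, 2.14, but this rests on Ccl6 (6.52% of the intestinal level) and Tff3 (1.23%), and for the other genes, with a ratio of 1.31 without these 2, carry-over is a candidate explanation. Intestine in the liver piece of the same mouse cannot be told apart, since 1 of 6 pairs of equal treatment and number had a Fabp6 ratio over 5 times from the median ratio, and the labels do not tie the libraries to animals. No other explanation was tested.

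The 7SL genes Rn7s1, Rn7s2 and Rn7s6 and the 7SK gene Rn7sk fell in LCWE livers. A general loss of short non-coding RNAs in those libraries is argued against, since 259 other tested short non-coding RNAs had a median log2 fold change of 0.024 (SE 0.055 over these RNAs). Of them 7 fell and 2 rose, while 93 fell and 489 rose among all 14404 tested genes. Falls thus outnumbered rises among these RNAs and not over all genes, so a loss of some of them stays open. Scaling of the libraries is argued against for the 7SL and 7SK genes, since 4 of these 4 were lower and passed under both scalings. A difference in library preparation that acts on the 7SL and 7SK RNAs, or on some short RNAs, stays open, as does a change in the livers. Neither was tested.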

How the results depend on the processing

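Of the settings below, limma voom on recovered reads was chosen after seeing the data, and all others were chosen before the data were examined. Where a result changed, the cause was not tested, except that a left-out library leaves fewer samples and that a stricter or absent filter changes the number of genes tested. Liver calls stayed within 1.5 times of the 582 with either pseudocount (518 and 608), a stricter filter (525), either scaling (465 and 478), robust moderation (565) and voom (730). Of the 56 named liver genes that passed, 54 passed with voom, 54 after quantile scaling, 52 after median-ratio scaling and 38 with no filter, and none changed direction in any setting run. The 6 genes named for the tissue difference passed in every setting run but the block and voom, where 5 did. The liver lists for acute phase, interferon, cytokines, pattern recognition, neutrophils, macrophages, T and NK cells, MHC class II, extracellular matrix, cholesterol, fatty acid oxidation and fatty acid synthesis, and the intestinal lists for enterocytes and adipose tissue, passed in every setting run but the estimated correlation. Depth was at least 30294594 reads in each library, and how the calls change with depth was not tested. The list tests were not run with robust moderation, the fold threshold or the single fit over 4 groups, and lists left with under 5 genes got no value. These were neutrophils in both tissues, intestinal erythroid markers and liver T and NK cells under the stricter filter, intestinal erythroid markers without PBS 2, PBS 4 or LCWE 2, and liver neutrophils and T and NK cells without any 1 of the LCWE libraries. In what follows PBS 2 stands for PBS replicate 2, and so on, and list values are adjusted p.

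Array weights, which gave intestinal PBS 3 and LCWE 2 weights of 6.10 and 5.91 and every other intestinal library 0.666 or less, moved the intestinal calls from 0 to 8636 (6476 rose, 2160 fell). They moved the liver calls from 582 to 1902 (1259 rose, 643 fell), the tissue difference from 137 to 4190 genes and the calls in both tissues from 0 to 748. The estimation of the weights stopped before it converged for the intestine and for the 4 groups together, and converged for liver alone. The intestinal counts, the tissue difference and the overlap with array weights are therefore unreliable. With 1 fit over 4 groups the intestinal calls were 243 (94 rose, 149 fell), the liver calls 987 (813 rose, 174 fell) and the calls in both tissues 9. With no filter the liver calls were 335, and with a fold of at least 2 they were 270. Median-ratio scaling gave 206 genes with a tissue difference. An unadjusted p in both tissues gave 388 genes with the same sign.

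Leaving out 1 library at a time gave from 0 (without PBS 2, for example) to 70 (without LCWE 1) intestinal calls. It gave from 55 (without LCWE 2) to 943 (without PBS 2) liver calls. The tissue difference ran from 20 genes (without liver PBS 3) to 461 genes (without intestinal LCWE 1). The number of intestinal lists past the threshold ran from 2 (without LCWE 2) to 10 (without LCWE 1), against 5.

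With an estimated correlation 0 intestinal and 0 liver lists passed. In the intestine the values were 0.953 for cell cycle, 0.953 for extracellular matrix, 0.737 for immediate early genes, 0.737 for enterocytes and 0.367 for adipose tissue. In liver they were 0.161 for acute phase, 0.0665 for interferon, 0.128 for cytokines, 0.0665 for pattern recognition, 0.0562 for neutrophils, 0.0562 for macrophages, 0.0665 for T and NK cells, 0.327 for B and plasma cells, 0.128 for MHC class II, 0.234 for erythroid markers, 0.128 for extracellular matrix, 0.0665 for cholesterol, 0.161 for fatty acid oxidation, 0.338 for fatty acid synthesis, 0.218 for bile acids, 0.133 for xenobiotic metabolism and 0.257 for secreted proteins.

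Array weights moved the number of intestinal lists past the threshold from 5 to 9. They brought in interferon (0.00105), macrophages (0.0125), antimicrobial genes (0.00560) and tight junctions (0.0296). They turned the direction of acute phase (0.531), MHC class II (0.838), cholesterol (0.453), ileal bile acids (0.813), enteroendocrine genes (0.489) and smooth muscle (0.144), none of which passed. In liver they ended the erythroid call (0.140), brought in complement (0.0225) and turned the cholangiocyte list (0.891). The log2 fold changes of intestinal Hbb-bs (0.21), Cela1 (0.014), Rn7s6 (0.11) and Cd74 (-0.027) changed sign.

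Quantile scaling moved the number of intestinal lists from 5 to 8, with macrophages at 0.0392, B and plasma cells at 0.0392 and goblet cells at 0.0175, and turned the Paneth list (0.865). In liver it ended the calls for erythroid markers (0.0517), bile acids (0.176), xenobiotic metabolism (0.0889) and secreted proteins (0.0521) and brought in complement (0.0294). Median-ratio scaling brought in intestinal macrophages (0.0213), B and plasma cells (0.0461) and goblet cells (0.0461), ended the call for immediate early genes (0.0603), and turned the log2 fold change of intestinal Cd74 to -0.050. With no filter, intestinal pattern recognition (0.0270), goblet cells (0.0270) and liver cell cycle (0.00253) passed, and liver B and plasma cells did not (0.289). The stricter filter ended the intestinal extracellular matrix call (0.0953) and turned the cytokine (0.975) and enteroendocrine (0.902) lists. With a pseudocount of 0.1 the log2 fold change of intestinal Cela1 turned to 0.0012.

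Among intestinal lists, leaving out 1 library changed the call or the direction of the following. The acute phase ran from 0.212 (without LCWE 4) to 0.719 (without PBS 2) and turned in both, interferon from 0.000953 (without LCWE 1) to 0.843 (without LCWE 2, turned), and cytokines from 0.576 (without PBS 2, turned) to 0.959 (without PBS 3). Macrophages ran from 0.000825 (without LCWE 1) to 0.279 (without LCWE 2), T and NK cells from 0.00334 (without PBS 2) to 0.695 (without PBS 4), and B and plasma cells from 0.0363 (without PBS 3) to 0.713 (without PBS 2). MHC class II ran from 0.194 (without LCWE 4) to 0.880 (without LCWE 2, turned), and erythroid markers from 0.130 (without LCWE 4) to 0.749 (without LCWE 1, turned). Cell cycle ran from 4.30e-05 (without PBS 2) to 0.301 (without PBS 4), extracellular matrix from 0.000677 (without LCWE 1) to 0.260 (without LCWE 4), and immediate early genes from 0.000720 (without PBS 2) to 0.137 (without LCWE 2). Cholesterol ran from 0.00422 (without PBS 4) to 0.483 (without PBS 3), and ileal bile acids from 0.371 (without PBS 4) to 0.843 (without LCWE 2). Goblet cells ran from 0.00681 (without LCWE 4) to 0.364 (without LCWE 1), and Paneth cells from 0.00681 (without LCWE 4) to 0.570 (without LCWE 1, turned). Antimicrobial genes ran from 0.00432 (without LCWE 1) to 0.283 (without LCWE 2), tight junctions from 0.0154 (without LCWE 1) to 0.886 (without LCWE 4), and stem cells from 0.0374 (without LCWE 1) to 0.649 (without LCWE 4). Enteroendocrine genes ran from 0.662 (without LCWE 1, turned) to 0.959 (without PBS 3), and smooth muscle from 0.130 (without LCWE 4, turned) to 0.526 (without LCWE 2). Between these ends, direction also turned for interferon and smooth muscle without PBS 2, for cytokines without LCWE 2 or LCWE 4, for MHC class II without PBS 4 or LCWE 1, for cholesterol without PBS 2 or LCWE 1, for ileal bile acids without LCWE 1, for tight junctions without LCWE 2 and for enteroendocrine genes without PBS 4 or LCWE 4.

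In liver, B and plasma cells ran from 0.00543 (without PBS 2) to 0.139 (without PBS 4), erythroid markers from 0.00216 (without PBS 3) to 0.309 (without PBS 2), and cell cycle from 0.0141 (without LCWE 1) to 0.650 (without LCWE 4). Immediate early genes ran from 0.00521 (without LCWE 4) to 0.709 (without LCWE 2), glucose metabolism from 0.00689 (without LCWE 4) to 0.471 (without PBS 2), and complement from 0.0470 (without PBS 2) to 0.921 (without PBS 4). Cholangiocytes ran from 0.419 (without PBS 3) to 0.903 (without LCWE 1) and turned without PBS 2. Among named intestinal genes, log2 fold changes that changed sign ran from -0.39 to 0.14 for Hba-a1, -0.39 to 0.14 for Hbb-bt, -0.29 to 0.20 for Hbb-bs and -0.43 to 0.12 for Clps, all turned without LCWE 1. They ran from -0.31 to 0.25 for Cela1, highest without PBS 2, and from -0.024 (without LCWE 1) to 0.16 for Cd74.

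The replicate numbers were not taken to pair the samples. Deviations of intestinal and liver libraries with the same number correlated between -0.05 and 0.08 across genes, where pairing was to need over 0.1 for each pair. Still, 5 of the 6 intestinal libraries correlated best with the liver library of their own number, and intestinal PBS 3 did so with liver PBS 2 (0.04), so a hint of shared animals stays open. Within a tissue only numbers 2 and 4 occur in both groups. There the block joined PBS and LCWE libraries of equal number, so its effect rested on numbers 2 and 4 alone. Such a fit cannot test for animals shared between the tissues. For the tissue difference the block instead joined the intestinal and liver libraries of equal treatment and number. With the replicate block there were 0 intestinal calls, 24 liver calls (12 rose, 12 fell), 12 genes with a tissue difference (9 above 0, 3 below) and 0 calls in both tissues. With the block, 11 intestinal lists passed against 5, with interferon at 0.000770, macrophages at 0.000729, B and plasma cells at 0.00618, antimicrobial genes at 0.000230, tight junctions at 0.0365 and smooth muscle at 0.00332. The block turned the intestinal lists for MHC class II (0.718), erythroid markers (0.540), cholesterol (0.240), ileal bile acids (0.863), Paneth cells (0.130) and enteroendocrine genes (0.718). In liver the block ended the call for B and plasma cells (0.0865) and brought in cell cycle (0.00702). It turned the log2 fold changes of intestinal Hba-a1 (0.30), Hbb-bt (0.39), Hbb-bs (0.20), Ctrl (0.079), Clps (0.22) and Cela1 (0.11). Of the 56 named liver genes that passed, 14 passed with the block, and Gm4070 did not pass for the tissue difference.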

Other observations

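The 3 gene lists below were chosen, and all tests of them made, after the liver results were seen, so each is a hypothesis tested on the data it came from.

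Genes of the unfolded protein response and of protein folding in the endoplasmic reticulum were higher in LCWE livers, with 10 of 20 tested members risen, 1 fallen, 19 higher and a median log2 fold change of 0.75. The list passed with a preset correlation (adjusted p = 2.19e-12 over the 3 lists) and not with an estimated one (p = 0.0462, adjusted p = 0.0693). Hspa5, the main chaperone of the endoplasmic reticulum, rose from 272 ± 55.3 to 718 ± 55.5 RPKM (mean ± SD, n = 3), 2.67-fold with an adjusted limma p of 0.0112. The chaperone genes Hyou1, Sdf2l1 and Hsp90b1 rose 3.13-fold, 2.98-fold and 2.14-fold, and Manf, a secreted stress protein, rose from 57.6 to 160 RPKM. Atf4, a transcription factor of the stress response, fell from 91.9 to 60.5 RPKM.

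Interferon-inducible GTPases, which act on vacuoles that hold pathogens, rose in all 12 tested members left after 4 of 16 were set aside as already named, with a median of 1.31. The list passed with a preset correlation (adjusted p = 7.62e-15) and not with an estimated one (p = 0.0282, adjusted p = 0.0693), and 4 of its members are also in the interferon response list. Tgtp2 rose from 1.88 to 10.6 RPKM, Igtp from 13.4 to 41.6 RPKM and Iigp1 from 70.0 to 113 RPKM. Several of these genes have near-identical copies, whose reads may be shared, so single members are uncertain even where the list's adjusted p is 7.62e-15.

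Genes of MHC class I presentation and of the immunoproteasome were all higher, with 8 of 17 risen and a median of 0.50. The list passed with a preset correlation (adjusted p = 1.72e-08) and not with an estimated one (p = 0.0714, adjusted p = 0.0714), and 1 member is also in the interferon response list. Tap1, which carries peptides to class I molecules, rose from 2.54 to 5.81 RPKM, Nlrc5, which drives class I genes, from 2.26 to 4.64 RPKM, and H2-D1 from 225 to 348 RPKM.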
